A study of Mus musculus with 30 samples.

How the data were processed

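RNA was extracted from mouse hearts and sequenced as paired reads of 150 bases from directional libraries, per the labels' protocols. The deposited values are raw counts per Ensembl gene, 1 file per library, made by the authors with bcl2fastq 2.20.0 and featureCounts on the genome build GRCm38, per the submitters' processing notes. The version of featureCounts, the aligner and the strand setting are not given in the sources used here. The values are whole numbers with different totals, from 7841930 to 14070017 counts per library. A gene with no count in a library may hold up to 3 counts, 0.213 to 0.383 CPM by library, and this limit covers counting error only. Symbols and positions came from a GRCm38 annotation, which names 97.3% of the 43629 gene identifiers and 99.9% of the counts. All 37 mitochondrially encoded genes had 0 counts as deposited, to which this limit does not apply, and 15265 genes had no count in any library.

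Libraries were grouped by operation and day as the labels give them. The MI and sham libraries of each day were compared in a fit of these 10 libraries, and the differences of the MI effect between days and the sham comparisons in 1 fit of all 30 libraries. Each fit used edgeR 4.0.16 in R 4.3.3, with filterByExpr (minimum count 10, minimum total 15), TMM factors and the robust quasi-likelihood F test, which is 2-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison were called. The labels give no statement that replicates with the same number belong together, so that no pairing was used. CPM were counts over the library total, and standard deviations are over the 5 libraries of a group.

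The comparisons, 40 gene lists of 544 genes, the rule for named genes and most alternatives were set before the data were examined. The lists came from general knowledge of the infarcted heart and share some members. The rule names 30 genes at each day whatever their result. It adds the 5 largest changes in each direction among called genes with a mean of at least 10 CPM (at each day also without overlap of the groups), and up to 2 called genes per list, with a mean of at least 1 CPM, at the day of its largest median. Not all genes of these last parts are named. Lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and with an estimated correlation, and p-values were adjusted over the lists and days of a family (113 tests for the 3 days, 80 for the differences between days and 80 for the sham comparisons). Counts of list genes past the threshold are given over all genes and adjusted over the list alone.

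Alternatives to these choices were median-ratio factors, DESeq2 1.42.0, limma voom with sample weights, no filter or a mean of at least 1 CPM, a test against a fold change of at least 1.5, the replicate number as a block, another choice of libraries in the fit, leaving out each library in turn, and leaving out mitochondrially encoded genes. Those that leave out libraries with lung transcripts (Sftpc and Scgb1a1 summing to at least 50 CPM), near-copies of mitochondrial genes (at least 90% identity over at least 50% of the transcript by blastn 2.17.0; 15 genes) or pseudogenes were chosen after seeing the data. Library measures were compared by exact permutation tests, 2-sided, in scipy 1.17.1 with Python 3.11.15. The fits were tested on simulated data with known changes: 88% of the genes changed 2-fold were called at each of the 3 days, 64 and 66% for the differences between days, and 80 and 72% in the sham comparisons. Of the genes called there, 3.53 to 7.48% had no simulated change. At each of the 3 days far fewer genes were changed in the simulation than were called in the data. The same held for the difference between days 2 and 4 and for sham day 4 against day 2. There 170 and 198 genes were called in the simulation, against 746 and 3795 in the data. For sham day 7 against day 4 more were called in the simulation, 185 against 19. The shares for all these comparisons therefore do not give the sensitivity of the real ones. Figures were drawn with matplotlib 3.10.9.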

Results

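RNA from the hearts of wild-type C57BL/6J mice was sequenced 2, 4 or 7 days after thoracotomy with ligation of a coronary artery (MI) or after the operation without the ligation (sham). The 30 libraries formed 6 groups of 5, MI and sham at each of the 3 days. Each held counts of 43629 genes, with totals from 7841930 to 14070017 counts and 18668 to 20905 genes detected. Values are given as CPM, counts scaled to a common library total. The Y-linked gene Ddx3y read 84.3 to 139 CPM in every library and Xist, transcribed from the inactive X chromosome of females, at most 0.707 CPM. The comparisons ask which genes differed between infarcted and sham hearts at each day, whether that difference changed between days, and how the sham hearts differed with time. The labels name the replicates of a group as separate samples without saying which part of the heart was taken, and the p-values measure the spread between these samples.

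On the first principal component, with 40.3% of the variance, the MI libraries of each day lay above the sham libraries of that day. At day 2 the scores ran from -62.5 to -45.7 in sham and from -8.50 to 9.67 in MI libraries, and at day 7 from -46.8 to -12.3 and from 35.9 to 78.3. The second component, with 25.4%, separated day 2 from the later days within each arm: the sham libraries lay between -29.9 and -18.8 at day 2 and between 23.5 and 52.9 at day 4. The 10 most counted genes took a smaller share of the counts in MI than in sham libraries, 8.02 against 10.2% at day 2, 7.12 against 11.2% at day 4 and 7.06 against 10.8% at day 7. Each of these differences had an exact permutation p of 0.00794, the smallest that 5 against 5 libraries allow (Benjamini-Hochberg adjusted p = 0.0397 over 15 tests). In the same exact permutation tests more genes were detected in MI than in sham libraries at days 2, 4 and 7 (adjusted p = 0.0446, 0.0446 and 0.0397). At day 4 the MI libraries also had larger totals and more of Gm42418, 4447 against 3452 CPM (exact permutation, adjusted p = 0.0397 for both).

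**Figure D1:**
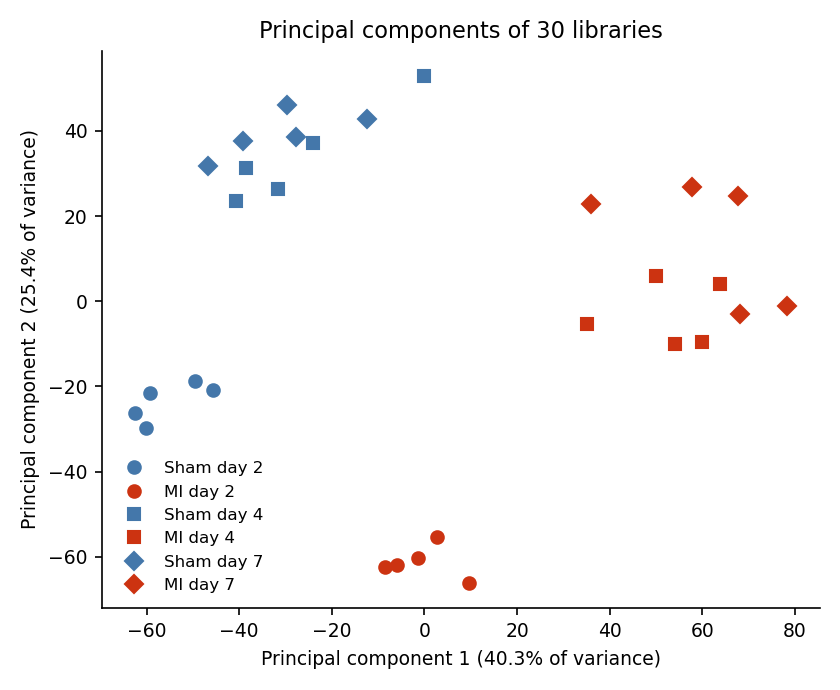
Principal components 1 (40.3% of the variance) and 2 (25.4%) of log2 CPM of 15537 genes in 30 libraries, with sham in blue and MI in red (circles day 2, squares day 4, diamonds day 7). At each day the 5 MI libraries lie to the right of the 5 sham libraries.

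Some libraries held transcripts of other tissues, read from genes chosen after their values were seen. Sftpc, a surfactant gene of alveolar cells, and Scgb1a1, a secretoglobin of airway cells, together read 168 and 410 CPM in sham day 4 replicates 2 and 3, 234, 392 and 263 CPM in sham day 7 replicates 1, 2 and 3, and 1642 CPM in MI day 7 replicate 2. The highest sum among the other libraries was 24.1 CPM, so that some of these held lung transcripts in smaller amounts. Genes of fast skeletal muscle stood out in MI day 7 replicate 4, with Myh1 at 288 CPM (0.431 CPM in the next highest library), Mylpf at 312 CPM (next 1.69) and Actn3 at 174 CPM (next 0.940). Sham day 4 replicate 3 had the highest Ucp1, the uncoupling protein of brown fat, at 62.1 CPM, and the highest Adipoq, the adipocyte hormone adiponectin, at 68.5 CPM. Fam221b read 85.7 to 122 CPM at day 2 and 0.804 to 4.08 CPM at days 4 and 7, whether or not the artery had been ligated. The 37 mitochondrially encoded genes had 0 counts as deposited in all 30 libraries. These zeros set no upper limit on their expression, as 15 near-copies of them in the nuclear genome held 0.655 to 4.01% of the counts. The near-copies held 1.96 to 4.01% in the day 2 libraries and 0.655 to 1.88% in those of days 4 and 7.

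**Figure D2:**
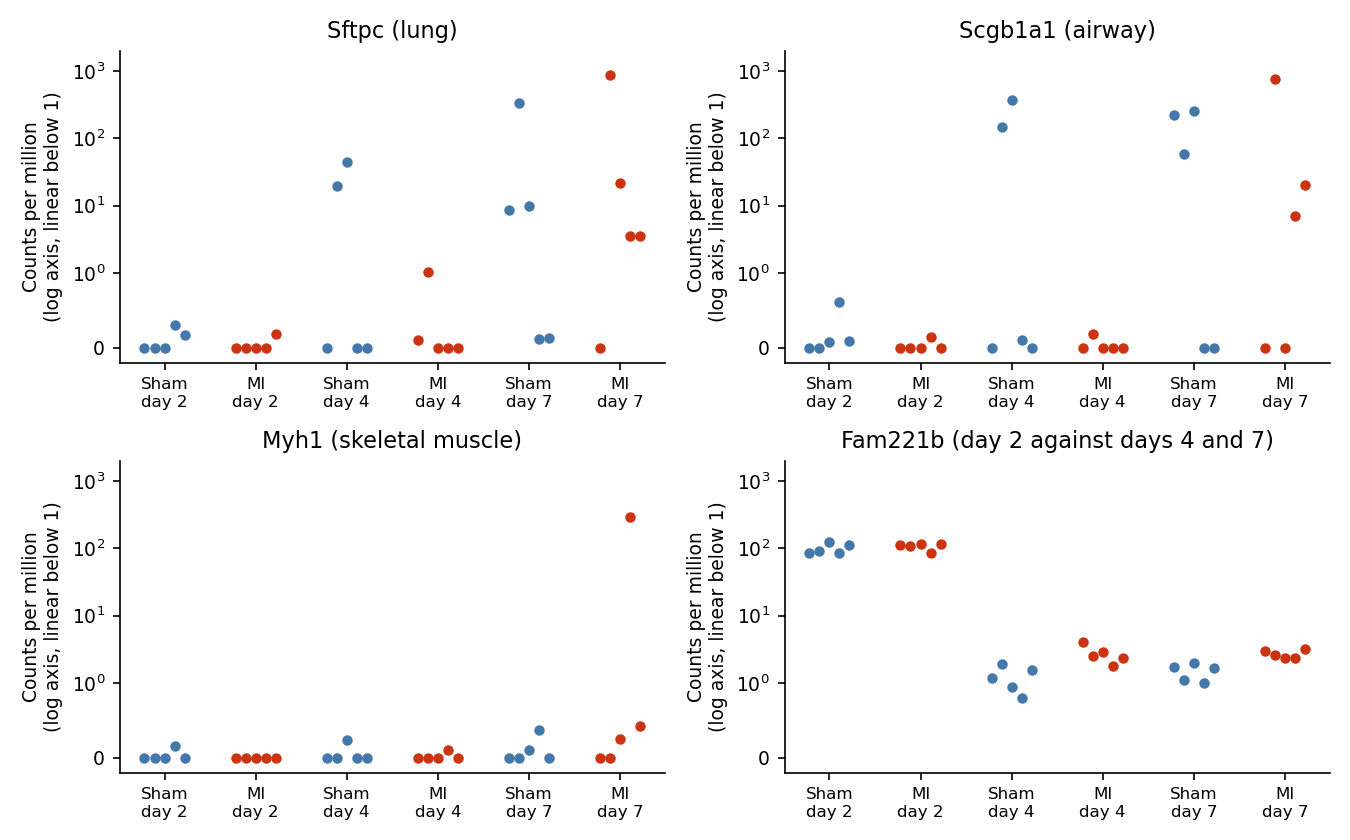
CPM of Sftpc, Scgb1a1, Myh1 and Fam221b in each library of the 6 groups (n = 5 each, sham blue, MI red), on a logarithmic axis that is linear below 1 CPM. Myh1 reaches 288 CPM in 1 MI library of day 7, and Fam221b lies at 85.7 to 122 CPM in the day 2 libraries and at most 4.08 CPM in the others.

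At day 2, MI libraries held more transcript of most neutrophil, monocyte and cytokine genes tested than sham libraries, and less of most contractile and calcium handling, ion channel and mitochondrial metabolism genes. With an estimated correlation in camera, the lists at this day had adjusted p of at least 0.269. S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035 in GRCm38), a subunit of the neutrophil protein calprotectin, averaged 104 ± 70.4 CPM in MI and 3.15 ± 1.33 CPM in sham libraries (SD, n = 5), 30.6-fold higher with an edgeR adjusted p of 1.92e-05. Nppb (ENSMUSG00000029019, chromosome 4, 147985788 to 147987205), which encodes B-type natriuretic peptide, was 4.49-fold higher at 2120 ± 446 CPM (SD, n = 5; edgeR adjusted p = 2e-05). Atp2a2 (ENSMUSG00000029467, chromosome 5, 122453513 to 122502225), the calcium pump of the sarcoplasmic reticulum, averaged 7698 ± 1480 against 18540 ± 1890 CPM (SD, n = 5), a log2 fold change of -1.36 ± 0.13 SE (edgeR adjusted p = 1.91e-06). Of 14524 genes tested, 3498 were higher and 3225 lower in MI libraries, 895 and 350 of them by at least 2-fold. The 5 MI and 5 sham values did not overlap in 62.2% of the called genes, a share raised by their selection on the same values.

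All 15 tested neutrophil genes were higher at day 2, with a median log2 fold change of 3.34. The interleukin 1 decoy receptor Il1r2 was 28.3-fold, the chemokine receptor Cxcr2 27.3-fold and S100a9, the partner of S100a8, 20.7-fold higher. All 12 inflammatory monocyte genes were higher, among them the arginine-degrading enzyme Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484) at 127 ± 14.9 against 11.9 ± 4.76 CPM (SD, n = 5). Of 17 tested cytokine and chemokine genes 13 were higher and 4 not past the threshold, among them Il1b at 20.4 against 2.39 CPM, the monocyte attractant Ccl2, 3.87-fold, and Il6, with a log2 fold change of 1.83. These 3 counts were the same when adjusted over the list alone, and camera gave each list an adjusted p = 0.269 with an estimated correlation. Of 12 pan-macrophage and leukocyte genes 10 were higher (median 0.80, adjusted p = 0.29 with an estimated correlation in camera). Of 13 genes of phagocytic and lipid-associated macrophages 8 were higher and 1 lower, both counts unchanged when adjusted over the list alone (camera adjusted p = 0.473 with an estimated correlation). They included the matricellular cytokine Spp1, 7.20-fold, and the lipid receptor Trem2, 2.31-fold higher. Lyve1, a marker of resident macrophages and lymphatic vessels, had a log2 fold change of 0.00 ± 0.15 SE (edgeR adjusted p = 0.995), and of 12 resident macrophage genes 3 were higher and 1 lower.

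Heart muscle genes moved both ways at day 2. Of 14 cardiac stress and fetal genes 11 were higher and 1 lower (median 1.16), with the same counts adjusted over the list alone. Ankrd1, a stress-responsive protein of the sarcomere and nucleus, was 2.55-fold higher, the atrial natriuretic peptide gene Nppa 1.26-fold (edgeR adjusted p = 0.0387) and skeletal actin Acta1 1.49-fold (edgeR adjusted p = 0.0322). Of 20 contractile and calcium handling genes 13 were lower and 2 higher, and 13 of 16 ion channel and connexin genes were lower (14 adjusted over the list alone). Myh6, the adult myosin heavy chain, averaged 3854 against 10270 CPM, 2.84-fold lower, and Kcnip2, a subunit of the transient outward potassium channel, fell by 1.73 on the log2 scale. Myh7, the fetal myosin heavy chain, had a log2 fold change of 0.22 (edgeR adjusted p = 0.585). Lower too were 17 of 25 fatty acid oxidation genes, 22 of 24 genes of the respiratory chain and TCA cycle (23 adjusted over the list alone) and 14 of 16 genes of branched-chain amino acid catabolism. The mitochondrial regulator Ppargc1a fell by 0.83 on the log2 scale, and Cpt1b, which admits fatty acids to mitochondria, fell by 0.39 (edgeR adjusted p = 0.0491). With an estimated correlation camera gave fatty acid oxidation an adjusted p = 0.473 and each of the 5 other lists an adjusted p = 0.269.

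Genes of repair and growth had begun to differ at day 2. Of 26 proliferation genes 24 were higher, and adjusted over the list alone 24 were higher and 1 lower (camera adjusted p = 0.528 with an estimated correlation). The mitotic marker Mki67 was higher by 1.14 and the topoisomerase Top2a by 1.20 on the log2 scale. Of 18 myofibroblast and matricellular genes 12 were higher and 1 lower (camera adjusted p = 0.376 with an estimated correlation), including the protease inhibitor Timp1, at 171 against 26.7 CPM, the matrix glycoprotein Tnc, 5.45-fold, and Cthrc1, a secreted protein of activated fibroblasts, 3.64-fold higher. Periostin (Postn) was 2.31-fold higher and the collagen crosslinking enzyme Lox 3.65-fold. Col1a1 and Col3a1, the fibrillar collagens, had log2 fold changes of 0.16 and -0.11 (edgeR adjusted p = 0.648 and 0.73), and smooth muscle actin Acta2 one of -0.08 (edgeR adjusted p = 0.792). Of 23 collagen genes 9 were higher and 1 lower (camera adjusted p = 0.672 with an estimated correlation). Of 10 resting fibroblast genes 7 were lower and 1 higher (camera adjusted p = 0.521 with an estimated correlation), while the fibroblast receptor Pdgfra had a log2 fold change of -0.14 (edgeR adjusted p = 0.562).

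Of 14 genes of the unfolded protein response 12 were higher at day 2 (median 0.74, camera adjusted p = 0.356 with an estimated correlation), among them the secreted survival factor Manf, 2.65-fold. Of 16 glycolysis genes 7 were higher and 2 lower (camera adjusted p = 0.647 with an estimated correlation), among them the lactate carrier Slc16a3, 6.05-fold higher, and of 14 hypoxia genes 5 were higher and 2 lower. All 3 tested platelet genes were higher, Ppbp 6.56-fold. Of 15 endothelial genes 7 were lower and 3 higher, of 10 pericyte and smooth muscle genes 6 lower and 1 higher, of 8 mesothelial genes 4 lower and of 8 Schwann cell genes 5 lower and 1 higher. With an estimated correlation camera gave pericyte and smooth muscle genes an adjusted p = 0.402 and mesothelial genes an adjusted p = 0.528. It gave 0.458, 0.59 and 0.297 for matrix proteases, erythroid and clock genes at this day (camera adjusted p with an estimated correlation). The carboxylesterase Ces1d and the myosin kinase Mylk4 had the lowest log2 fold changes among genes of at least 10 CPM without overlap of the groups, -2.53 and -2.38. Nppa lost its call without sham day 2 replicate 2 or 4 or MI day 2 replicate 1, 2, 4 or 5 (log2 fold changes 0.24, 0.29, 0.34, 0.30, 0.26 and 0.33), and Cpt1b without sham day 2 replicate 1, 2 or 4 or MI day 2 replicate 1, 2 or 3 (-0.37, -0.34, -0.36, -0.38, -0.28 and -0.35). Acta1 lost its call without sham day 2 replicate 3, 4 or 5 or MI day 2 replicate 4 or 5 (0.61, 0.53, 0.59, 0.46 and 0.51), and Top2a without sham day 2 replicate 3 (1.08). A model over all 30 libraries ended the calls of Nppa, Cpt1b and Acta1 (edgeR adjusted p = 0.17, 0.0655 and 0.157), and fitting without a filter on low counts those of Cpt1b, Acta1, Mki67 and Top2a (edgeR adjusted p = 0.0965, 0.124, 0.0567 and 0.0654).

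**Figure D3:**
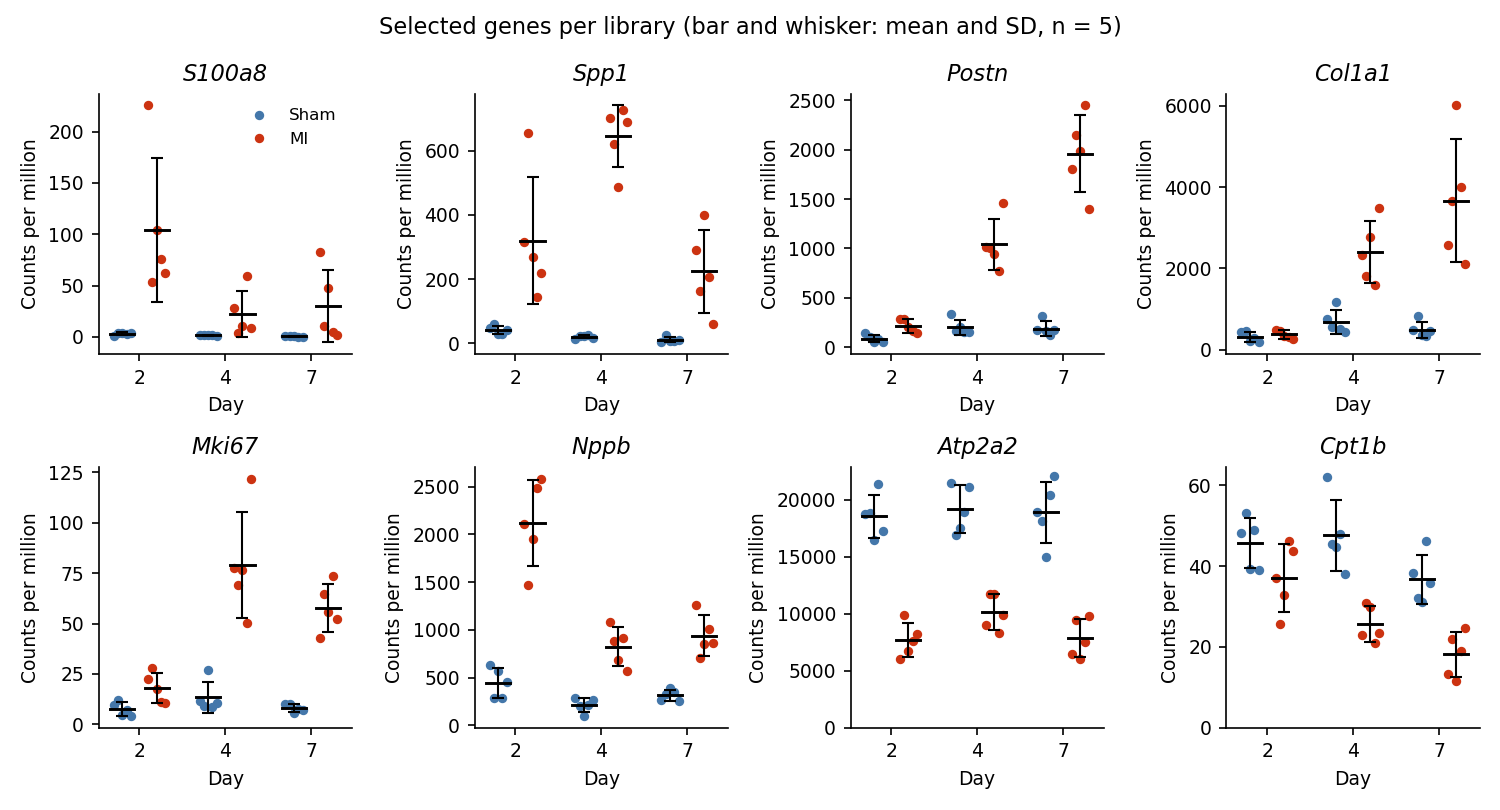
CPM of S100a8, Spp1, Postn, Col1a1, Mki67, Nppb, Atp2a2 and Cpt1b in each library at days 2, 4 and 7 (sham blue, MI red, points single libraries, bars mean ± SD, n = 5). Postn averages 217, 1041 and 1957 CPM in MI libraries at days 2, 4 and 7.

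At day 4, MI libraries held more transcript of macrophage, cell cycle, myofibroblast and collagen genes than sham libraries, and less of genes for fatty acid oxidation, the respiratory chain and contraction. The lists at day 4 had camera adjusted p of at least 0.269 with an estimated correlation. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050) averaged 645 ± 96.2 CPM in MI and 20.4 ± 4.80 CPM in sham libraries (SD, n = 5), 27.8-fold higher with an edgeR adjusted p of 5.17e-10. Sprr1a (ENSMUSG00000050359, chromosome 3, 92483952 to 92485895), a stress-induced protein first known from the epidermis, was 87.3-fold higher at 209 ± 38.9 against 2.10 ± 1.37 CPM (SD, n = 5; edgeR adjusted p = 2.17e-07). Of 14410 genes tested, 3968 were higher and 3629 lower, 1432 and 480 of them by at least 2-fold. The 5 MI and 5 sham values did not overlap in 66.1% of the called genes, which were selected on the same values.

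Of 14 genes of phagocytic and lipid-associated macrophages 13 were higher and 1 lower at day 4 (median 2.46), among them the lysosomal glycoprotein Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), 15.2-fold, and Trem2, 5.61-fold. All 12 pan-macrophage and leukocyte genes and all 12 inflammatory monocyte genes were higher, the latter including the chitinase-like protein Chil3, 9.92-fold, and Arg1, 7.39-fold. Of 16 cytokine and chemokine genes 15 were higher, with Il1b 16.2-fold, Il6 10.8-fold and Ccl2 7.41-fold. These counts held adjusted over the list alone, and camera gave each of the 4 lists an adjusted p = 0.269 with an estimated correlation. Of 13 neutrophil genes 12 were higher (camera adjusted p = 0.458 with an estimated correlation), S100a8 13.7-fold and S100a9 12.0-fold. S100a8 averaged 22.3 ± 22.8 CPM (SD, n = 5). Without MI day 4 replicate 4 the log2 fold changes of S100a8 and S100a9 were 2.98 and 2.97, in place of 3.77 and 3.58. Of 20 interferon-stimulated genes 12 were higher (camera adjusted p = 0.628 with an estimated correlation). Of 12 resident macrophage genes 4 were higher and 2 lower, with Lyve1 at a log2 fold change of -0.09 (edgeR adjusted p = 0.663). Of 14 complement genes 6 were higher, while the median was -0.26, the mean 0.40 and the direction of the camera test up. Without sham day 4 replicate 3, which held lung and fat transcripts, the complement median was 0.35.

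Of 26 proliferation genes 25 were higher at day 4, the cyclin Ccna2 7.08-fold, the mitotic checkpoint kinase Bub1 6.96-fold, Top2a 5.64-fold and Mki67 5.29-fold. All 18 myofibroblast and matricellular genes were higher, with Tnc 12.1-fold, Timp1 7.88-fold, Cthrc1 6.27-fold, Postn 4.55-fold and Acta2 1.49-fold (edgeR adjusted p = 0.0206). With an estimated correlation camera gave both lists an adjusted p = 0.269. Of 24 collagen and collagen processing genes 22 were higher (23 adjusted over the list alone, camera adjusted p = 0.376 with an estimated correlation), including Lox 6.41-fold. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) averaged 2392 ± 760 CPM against 681 ± 299 CPM (SD, n = 5), 3.13-fold higher, and Col3a1 was 2.35-fold higher. Of 15 matrix proteases and inhibitors 10 were higher and 1 lower (camera adjusted p = 0.277 with an estimated correlation). Pdgfra had a log2 fold change of 0.07 (edgeR adjusted p = 0.762), and 6 of 10 resting fibroblast genes were lower and 2 higher.

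Lower at day 4 were 24 of 25 fatty acid oxidation genes (median -1.17), all 24 genes of the respiratory chain and TCA cycle (median -0.85) and all 16 genes of branched-chain amino acid catabolism (median -0.94), with the same counts adjusted over the list alone. Camera gave them adjusted p = 0.277, 0.285 and 0.269 with an estimated correlation. Cpt1b fell by 1.07 and Ppargc1a fell by 1.04 on the log2 scale. Of 20 contractile genes 17 were lower and of 16 ion channel genes 14, each with a camera adjusted p = 0.269 with an estimated correlation. Myh6 fell by 1.19, Atp2a2 fell by 1.10 and Kcnip2 fell by 1.27 on the log2 scale. Of 13 stress and fetal genes 12 were higher (camera adjusted p = 0.269 with an estimated correlation), the growth factor Gdf15 11.0-fold, the nicotinamide riboside kinase Nmrk2 9.42-fold, Nppb 3.44-fold, Ankrd1 by 1.59 on the log2 scale, Nppa 2.46-fold and Acta1 2.32-fold. Myh7 had a log2 fold change of 0.18 (edgeR adjusted p = 0.547). Of 14 circadian clock genes 8 were lower (camera adjusted p = 0.269 with an estimated correlation), the clock output factor Dbp by a log2 fold change of -1.73 and the clock repressor Nr1d1 by one of -1.33.

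The 6 atrial, 8 mesothelial and 6 adipocyte genes tested at day 4 were not past the threshold (medians -0.22, -0.71 and -1.12), nor were the 6 erythroid genes and the 1 lung gene tested. Mesothelial scores, means of log2 CPM with 1 added, were 3.60 and 4.64 in sham replicates 2 and 3, which held lung transcripts. They were 2.11 to 2.85 in the other sham and 1.68 to 3.65 in the MI libraries. Adipocyte scores were 4.73 and 5.85 in these 2 replicates, 1.48 to 2.29 in the other sham and 0.91 to 3.62 in the MI libraries. Of 7 tested B cell genes 1 was higher, with a median of -0.51 and a camera direction of up, and the erythroid median and mean, -0.02 and 0.04, also differed in sign. The B cell score was 2.10 and 3.06 in sham replicates 2 and 3, 0.77 to 1.05 in the other sham libraries and 1.14 to 1.88 in the MI libraries. Of 14 genes of the unfolded protein response 9 were higher and 1 lower (camera adjusted p = 0.297 with an estimated correlation). The Acta2 call was lost without sham day 4 replicate 2 or 5 or MI day 4 replicate 1 or 5 (log2 fold changes 0.52, 0.51, 0.52 and 0.53).

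At day 7, genes of collagens, matricellular proteins and a late scar matrix were higher in MI than in sham libraries, together with MHC class II and interferon-stimulated genes, while metabolic and contractile genes were lower. With an estimated correlation camera gave MHC class II and interferon-stimulated genes an adjusted p = 0.528 each, and the other lists at day 7 at least 0.269. Postn (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037) averaged 1957 ± 391 CPM in MI and 190 ± 74.6 CPM in sham libraries (SD, n = 5), 9.04-fold higher with an edgeR adjusted p of 7.89e-07. Col1a1 averaged 3663 ± 1520 against 490.2 ± 198 CPM (SD, n = 5), 6.56-fold higher (edgeR adjusted p = 1.5e-05). Acaa2 (ENSMUSG00000036880, chromosome 18, 74779197 to 74806208), the thiolase of mitochondrial fatty acid oxidation, averaged 375 ± 75.3 against 992 ± 72.3 CPM (SD, n = 5), a log2 fold change of -1.60 ± 0.14 SE (edgeR adjusted p = 2.53e-06). Of 14492 genes tested, 4119 were higher and 3857 lower, 1765 and 675 of them by at least 2-fold. The 5 MI and 5 sham values did not overlap in 67.9% of the called genes, which were selected on the same values.

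All 24 collagen and collagen processing genes were higher at day 7 (median 2.31), Col11a1 55.4-fold, Col12a1 17.2-fold, Lox 14.1-fold and Col3a1 4.10-fold. All 18 myofibroblast and matricellular genes were higher (median 2.80), with the latent TGF-beta binding protein Ltbp2 18.0-fold, Cthrc1 at 183.8 against 12.4 CPM, Tnc 9.44-fold, Timp1 7.13-fold and Acta2 1.82-fold. Of 9 tested genes of late scar and cartilage-like matrix 7 were higher and 1 lower (2 lower adjusted over the list alone), the proteoglycan Acan 15.6-fold and the matricellular Ccn5 9.59-fold. On the log2 scale Acan changed by 4.96 without sham day 7 replicate 1, in place of 3.97, and Tnc by 3.98 without sham day 7 replicate 2, in place of 3.24. Of 15 matrix proteases and inhibitors 13 were higher, among them the membrane protease Mmp14, 5.09-fold. Camera gave each of these 4 lists an adjusted p = 0.269 with an estimated correlation. Of 10 resting fibroblast genes 5 were higher and 1 lower, and Pdgfra was 1.63-fold higher. Of 26 proliferation genes 25 were higher (camera adjusted p = 0.269 with an estimated correlation), Mki67 6.19-fold and Top2a 5.54-fold.

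All 25 fatty acid oxidation genes, all 24 genes of the respiratory chain and TCA cycle and all 16 genes of branched-chain amino acid catabolism were lower at day 7, also when adjusted over the list alone (medians -1.28, -1.02 and -1.08). Camera gave each an adjusted p = 0.269 with an estimated correlation. The uncoupling protein Ucp3 fell by 1.99 on the log2 scale, Cpt1b fell by 1.21 and Ppargc1a fell by 1.11. Of 20 contractile genes 16 were lower (camera adjusted p = 0.269 with an estimated correlation) and of 16 ion channel genes 14 (camera adjusted p = 0.285 with an estimated correlation). The modulatory potassium channel subunit Kcnv2 fell by 2.91 on the log2 scale, Kcnip2 fell by 1.88, Atp2a2 fell by 1.46 and Myh6 fell by 1.05. The sodium channel subunit Scn4b fell by 2.43. Of 13 stress and fetal genes 11 were higher (camera adjusted p = 0.269 with an estimated correlation), with Nppb 2.61-fold, Myh7 2.47-fold, Ankrd1 2.33-fold and Nppa 1.99-fold. Sprr1a, on none of the lists, was 232-fold higher. Of 16 glycolysis genes 6 were higher and 5 lower, with a median of -0.02, a mean of 0.17 and a camera direction of up. Of 14 hypoxia genes 2 were higher and 4 lower, with a median of 0.11 and a camera direction of down.

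Leukocyte genes stayed higher at day 7. All 12 pan-macrophage and leukocyte genes (camera adjusted p = 0.277 with an estimated correlation) and all 12 inflammatory monocyte genes (camera adjusted p = 0.342 with an estimated correlation) were higher, the signalling adaptor Tyrobp 4.83-fold and Arg1 3.84-fold. Of 14 genes of phagocytic macrophages 12 were higher and 1 lower (13 and 1 adjusted over the list alone, camera adjusted p = 0.376 with an estimated correlation), Spp1 17.6-fold and Trem2 7.23-fold. All 8 tested MHC class II genes were higher (median 0.76, camera adjusted p = 0.528 with an estimated correlation), with the class II transactivator Ciita 2.40-fold. The MHC class II score, a mean of log2 CPM with 1 added, was 5.11 in MI day 7 replicate 4, which held skeletal muscle transcripts, 4.77 in replicate 2, which held lung transcripts, and 4.26 to 4.54 in the other 3. Of 20 interferon-stimulated genes 16 were higher (camera adjusted p = 0.528 with an estimated correlation), the antiviral GTPase Mx1 3.98-fold, and of 14 complement genes 11 (camera adjusted p = 0.376 with an estimated correlation), the receptor C3ar1 3.38-fold. Of 13 cytokine and chemokine genes 10 were higher (camera adjusted p = 0.458 with an estimated correlation), Il6 14.9-fold, Il1b 11.6-fold and Ccl2 4.09-fold. Of 10 neutrophil genes 8 were higher (9 adjusted over the list alone), S100a8 41.2-fold at 29.7 ± 35.1 CPM (SD, n = 5) and S100a9 29.8-fold. Sham libraries of this day held 0.251 to 1.23 CPM of S100a8, 0.128 to 3.25 CPM of S100a9 and 0 to 0.785 CPM of Il6. The lowest of these values lie below the limit for a gene with no count, so these folds rest on few sham counts. Without MI day 7 replicate 1 the log2 fold changes of S100a8, S100a9 and Il1b were 4.50, 3.66 and 2.83, in place of 5.36, 4.90 and 3.53. Without sham day 7 replicate 2 those of S100a9, Il1b and Spp1 were 5.94, 4.19 and 4.75, where Spp1 had 4.14 with it. Of 12 resident macrophage genes 6 were higher and 1 lower, the scavenger receptor Mrc1 2.33-fold, while Lyve1 had a log2 fold change of 0.23 (edgeR adjusted p = 0.267). Of 7 dendritic cell genes 3 were higher and 1 lower, of 3 T cell genes 1 and 1, and of 8 B cell genes 5 were higher and none lower (7 higher adjusted over the list alone). In MI day 7 replicate 4 the B cell score was 3.66, and among the other MI libraries of this day it was highest in replicate 2, at 2.62. Without MI day 7 replicate 4 the B cell genes Cd79b and Ms4a1 had log2 fold changes of 1.15 and 0.83 and lost their calls (edgeR adjusted p = 0.0627 and 0.174). Each also lost its call under several other alternatives. None of the 10 NK and cytotoxic cell genes was abundant enough to be tested at any of the 3 days.

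All 6 erythroid genes were higher at day 7, where haemoglobin paralogues share reads (camera adjusted p = 0.576 with an estimated correlation). Of 6 atrial genes 2 were lower, of 11 immediate-early genes 1 higher and 3 lower, of 8 mesothelial genes 1 higher, and of 7 adipocyte genes 1 lower, while the 6 lung genes were not past the threshold (median 1.19). The skeletal muscle list had 2 tested genes and 1 higher, the fast troponin Tnnt3, at 143 ± 244 CPM (SD, n = 5). Without MI day 7 replicate 4, which held the skeletal muscle transcripts, Tnnt3 had a log2 fold change of 4.76 (edgeR adjusted p = 3.88e-06) in place of 6.82. Acta1 had a log2 fold change of 0.87 (edgeR adjusted p = 0.0922) and passed the threshold without MI day 7 replicate 1, at 1.08 (edgeR adjusted p = 0.0263), and in one model over all 30 libraries, at 0.88 (edgeR adjusted p = 0.0186). Its highest value, 2089 CPM, was in MI day 7 replicate 4, where the other MI libraries of this day had 372 to 1336 CPM. The fit without the 4 libraries of this day past the limit for lung transcripts leaves 2 sham libraries. There S100a8, S100a9, Il1b and Tnnt3 no longer passed (edgeR adjusted p = 0.142, 0.151, 0.0978 and 0.0993), at larger log2 fold changes of 6.78, 7.44, 4.55 and 7.93. Il6, Acan, Tyrobp, Top2a and Tnc passed there at 5.24, 5.83, 2.91, 3.12 and 3.84, in place of 3.90, 3.97, 2.27, 2.47 and 3.24. In limma voom S100a9 and Tnnt3 did not pass (limma voom adjusted p = 0.0661 and 0.0668), at 3.74 and 5.89, and S100a8 did at 3.88 (limma voom adjusted p = 0.0399). Tnnt3 had no adjusted p in DESeq2, at 6.86, and with a replicate block it was at 5.85 (edgeR adjusted p = 0.00373).

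**Figure D4:**
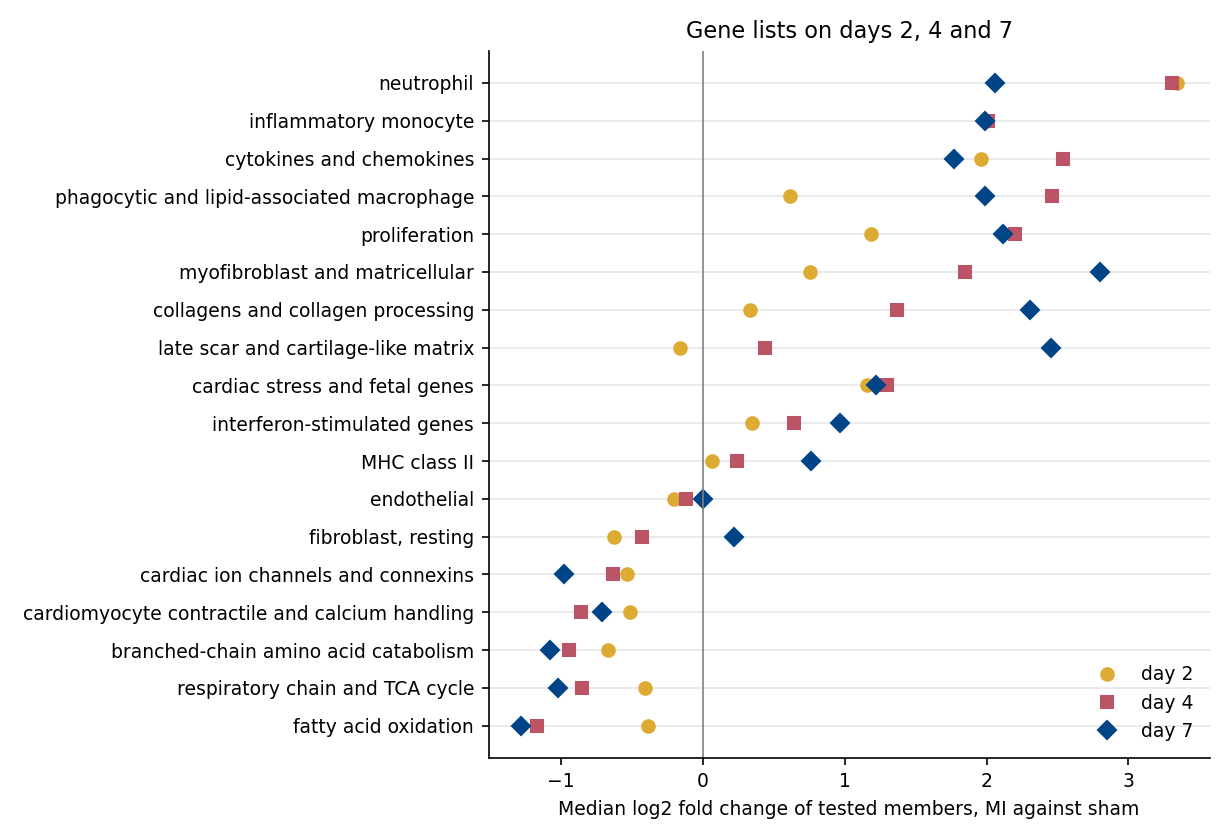
Median log2 fold change of MI against sham over the tested members of 18 gene lists at day 2 (circles), day 4 (squares) and day 7 (diamonds). The collagen list has medians of 0.33, 1.37 and 2.31 and the fatty acid oxidation list of -0.39, -1.17 and -1.28.

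Most genes that differed did so in the same direction at several days. Of 13953 genes tested at all 3 days, 2155 were higher and 1988 lower in MI libraries at each day. Days 2 and 4 shared 2596 higher genes, where 932 would be shared if the lists were independent, and 2316 lower genes (822 if independent). Days 4 and 7 shared 3104 higher genes (1108 if independent) and 2886 lower genes (975 if independent), with 19 in opposite directions. Between days 2 and 7, 2297 higher and 2241 lower genes were shared (948 and 875 if independent), and 177 moved in opposite directions. Across the 113 tests of the lists at the 3 days, 59 passed with the preset correlation in camera. With an estimated correlation 0 did in camera, with 17 at an unadjusted p under 0.05 and a smallest adjusted p of 0.269.

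The second question was whether the MI effect differed between days. From day 2 to day 4 it became more positive for the collagens Col1a1 and Col3a1 and the lysosomal glycoprotein Gpnmb, and more negative for most genes of fatty acid oxidation. Gpnmb averaged 9.65 ± 7.88 CPM in MI libraries of day 2 and 108 ± 20.3 CPM at day 4 (SD, n = 5), against 6.09 ± 2.18 and 6.36 ± 2.36 CPM in sham libraries, so that its log2 fold change was 3.37 ± 0.76 SE larger (edgeR adjusted p = 0.0114), and 4.002 larger without MI day 2 replicate 2. The growth factor Ptn gained 2.18 and the protease inhibitor Serpinb1a 2.12 on the log2 scale. The effect on the transferrin receptor Tfrc fell by 2.01 and that on the desaturase Scd4 fell by 2.57 (fell by 1.76 without sham day 4 replicate 1), while the thioesterases Acot1 and Acot2, near-identical copies whose reads cannot be assigned with certainty, had differences of -2.05 and -2.15. Of 15537 genes, the effect rose for 390 and fell for 356, while it rose for 351 and fell for 445 with median-ratio factors and rose for 515 and fell for 685 in DESeq2.

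Among the lists, the effect fell for 17 of 25 fatty acid oxidation genes (23 adjusted over the list alone, median difference -0.86, camera adjusted p = 0.205 with an estimated correlation). It fell for 7 of 24 genes of the respiratory chain and TCA cycle (19 adjusted over the list alone, camera adjusted p = 0.232 with an estimated correlation). It rose for 7 of 14 phagocytic macrophage genes (11 adjusted over the list alone, camera adjusted p = 0.224 with an estimated correlation), for 11 of 24 collagen genes (23 adjusted over the list alone, camera adjusted p = 0.309 with an estimated correlation) and for 7 of 18 myofibroblast genes (9 adjusted over the list alone, camera adjusted p = 0.224 with an estimated correlation). Of 26 proliferation genes it rose for 3 (19 adjusted over the list alone, camera adjusted p = 0.437 with an estimated correlation). Col1a1, Col3a1 and Nppa had larger effects at day 4, by 1.497, 1.36 and 0.98 on the log2 scale (edgeR adjusted p = 0.0455, 0.0396 and 0.0238). Whether the calls of these genes hold under the alternatives was not examined. Between days 2 and 4 the Nppa mean went from 1614 to 877 CPM in sham and from 2165 to 2433 CPM in MI libraries. Over the same days the mean of the atrial light chain Myl7 fell in both arms. It went from 574 to 356 CPM in sham and from 387 to 247 CPM in MI libraries. The differences for Spp1 (1.96, edgeR adjusted p = 0.0545) and S100a8 (-1.16, edgeR adjusted p = 0.69) did not pass. The total of 746 genes was 1200 in DESeq2, 1796 in limma voom, 475 without a filter on low counts and 19 against a fold change of at least 1.5. It was 462 without sham day 2 replicate 2, 1171 and 416 without MI day 2 replicates 2 and 4, 477, 1236 and 421 without sham day 4 replicates 2, 3 and 4, and 493 and 448 without MI day 4 replicates 1 and 5.

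From day 4 to day 7 the MI effect became more positive for some genes of late scar and cartilage-like matrix. Comp (ENSMUSG00000031849, chromosome 8, 70373558 to 70382066), cartilage oligomeric matrix protein, averaged 31.2 ± 11.5 CPM in MI libraries of day 4 and 130 ± 18.4 CPM at day 7 (SD, n = 5), against 16.9 ± 7.28 and 15.0 ± 1.71 CPM in sham libraries, a difference of effects of 2.23 ± 0.34 SE on the log2 scale (edgeR adjusted p = 0.000707). Col8a2, a short-chain collagen, gained 2.71, the Wnt-binding protein Sfrp2 2.16 and the collagen-binding proteoglycan Fmod 2.12. The effect on Dbp rose by 2.17, where the sham mean went from 29.7 ± 7.58 to 12.6 ± 2.76 CPM (SD, n = 5). The effect on the chromatin protein Hmga1 and its near-identical copy Hmga1b, whose reads cannot be assigned with certainty, fell by 0.88 and fell by 0.85. Of 15537 genes, the effect rose for 109 and fell for 49.

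The effect rose for 5 of 9 late scar genes (6 adjusted over the list alone, camera adjusted p = 0.138 with an estimated correlation), for 4 of 10 resting fibroblast genes (8 adjusted over the list alone, camera adjusted p = 0.138 with an estimated correlation) and for 4 of 18 myofibroblast genes (12 adjusted over the list alone, camera adjusted p = 0.232 with an estimated correlation). For the collagens it rose for 1 of 24 (17 adjusted over the list alone, camera adjusted p = 0.309 with an estimated correlation). The 25 fatty acid oxidation genes had a median difference of -0.07 and were not past the threshold over all genes or adjusted over the list alone. The difference for Myh7, 1.14 on the log2 scale, did not pass (edgeR adjusted p = 0.199), nor did those for Postn (1.01, edgeR adjusted p = 0.209) and Col1a1 (1.09, edgeR adjusted p = 0.242). The total of 158 genes was 421 in DESeq2 (224 higher and 197 lower), 268 in limma voom, 84 without a filter, 89 with only the libraries compared, 11 against a fold change of at least 1.5 and 18 without the libraries with lung transcripts, where Comp and Col8a2 still passed and Sfrp2, Fmod, Dbp and Hmga1 did not (edgeR adjusted p = 0.103, 0.155, 0.0751 and 0.0573), at differences of 2.41, 2.41, 2.199 and -0.85. Fmod also lost its call without a filter and with only the libraries compared (edgeR adjusted p = 0.0544 and 0.068). It was 97 and 70 without sham day 4 replicates 1 and 3, 76, 73 and 288 without MI day 4 replicates 1, 2 and 5, 99, 95 and 73 without sham day 7 replicates 1, 4 and 5, and 98, 95 and 294 without MI day 7 replicates 2, 4 and 5.

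The last comparisons asked how the sham hearts differed with time. Between days 2 and 4 the sham libraries differed in 3795 of 15537 genes, among them most interferon-stimulated and erythroid genes tested and many pseudogenes. The lists of the sham comparisons had camera adjusted p of at least 0.725 with an estimated correlation. Ankrd1 was lower at day 4 than at day 2 by a log2 fold change of -1.40, Nppb by one of -1.08, Nppa by -0.91 and Myh7 by -1.25, while Postn, Cthrc1 and Col1a1 were higher by 1.19, 1.52 and 1.09. The mean of the atrial light chain Myl7 went from 574 to 356 CPM between the same groups and that of the atrial calcium pump regulator Sln from 177 to 139 CPM. Of 20 interferon-stimulated genes 17 were higher at day 4 (camera adjusted p = 0.875 with an estimated correlation), as were all 6 erythroid genes (camera adjusted p = 0.725 with an estimated correlation) and all 7 adipocyte genes (camera adjusted p = 0.875 with an estimated correlation). The adipocyte score was 4.73 and 5.85 in sham day 4 replicates 2 and 3, which held lung transcripts, and 1.48, 1.62 and 2.29 in replicates 1, 4 and 5. Of 18 myofibroblast genes 7 were higher (9 adjusted over the list alone, camera adjusted p = 0.875 with an estimated correlation). Fam221b (ENSMUSG00000043633, chromosome 4, 43659622 to 43669145) averaged 99.6 ± 16.9 CPM at day 2 and 1.28 ± 0.46 CPM at day 4 (SD, n = 5), a log2 fold change of -6.29 ± 0.19 SE. Rps7 fell by 4.21 and Cox6c2 fell by 4.95 on the log2 scale, where reads of close copies cannot be assigned with certainty. Of 15537 genes, 1819 were higher and 1976 lower at day 4, against 1933 and 1864 with median-ratio factors. With the replicate number as a block they were 204 and 364, a total of 568. The block had its own terms in each day, so that fit compared the fitted levels of replicate 1 between days. It is no check of the difference between group means.

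The day 2 libraries carried another library prefix than those of days 4 and 7, so the difference between these days and the difference between prefixes cannot be told apart. The airway genes Bpifa1 and Scgb1a1, the immunoglobulin genes Jchain and Igkc and the desaturase Scd1 were higher at day 4, by 11.65, 9.10, 4.80, 4.45 and 4.59 on the log2 scale, with lung transcripts in sham day 4 replicates 2 and 3. Without the libraries with lung transcripts none of these 5 passed (edgeR adjusted p = 0.925, 0.744, 0.877, 0.798 and 0.148) and the total of 3795 genes was 2253. Scgb1a1, Jchain and Igkc changed direction there, at -1.92, -0.88 and -0.87, and Bpifa1 and Scd1 were at 0.76 and 1.52. The fit with a replicate block compares the fitted levels of replicate 1 between days, not the group means. There Bpifa1, Scgb1a1, Jchain, Igkc and Scd1 were at 1.13, 0.46, 2.53, 1.49 and 1.70 and none passed (edgeR adjusted p of at least 0.675). By limma voom only Scd1 passed, at 2.71 (limma voom adjusted p = 0.0122), while Bpifa1, Scgb1a1, Jchain and Igkc were at 4.17, 2.58, 1.78 and 1.57 (limma voom adjusted p of at least 0.58). With only the libraries compared, Igkc did not pass (edgeR adjusted p = 0.0811). Without sham day 4 replicate 3 alone, Scgb1a1, Jchain and Igkc lost their calls, at 7.72, 3.42 and 2.98, and Bpifa1 and Scd1 were at 10.13 and 3.16. Bpifa1 was at 12.36 in DESeq2 and 12.96 without sham day 2 replicate 3 and Scgb1a1 at 10.83 without sham day 2 replicate 4. Against a fold change of at least 1.5 the total was 668.

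Between days 4 and 7, 8 genes were higher and 11 lower in sham libraries. Adam19, a membrane protease, averaged 64.0 ± 18.3 CPM at day 4 and 115 ± 23.6 CPM at day 7 (SD, n = 5), a log2 fold change of 0.84 ± 0.15 SE (edgeR adjusted p = 0.0127). Wwtr1, a coactivator of the Hippo pathway, was higher by 0.45, and the tubulin gene Tuba4a was lower by a log2 fold change of -0.91 (edgeR adjusted p = 0.00828). All 6 atrial genes were higher when adjusted over the list alone and not past the threshold over all genes (median 0.75, camera adjusted p = 0.725 with an estimated correlation). The total of 19 genes was 110 in DESeq2, 86 in limma voom, 12 without a filter, 5 with only the libraries compared, 0 against a fold change of at least 1.5 (83 at an unadjusted p under 0.05 in edgeR) and 0 without the libraries with lung transcripts (690 at an unadjusted p under 0.05 in edgeR), where Adam19, Wwtr1 and Tuba4a were at 0.45, 0.29 and -0.94. Without single libraries it was 12, 12 and 12 (MI day 2 replicate 1, MI day 4 replicate 1, MI day 7 replicate 4), 2, 12, 0 and 31 (sham day 4 replicates 2, 3, 4 and 5) and 0, 1 and 9 (sham day 7 replicates 1, 3 and 5), with 1466 and 1400 genes at an unadjusted p under 0.05 in edgeR where it was 0. Adam19 lost its call without sham day 4 replicate 2 or 4 or sham day 7 replicate 1 or 3 (log2 fold changes 0.78, 0.81, 0.73 and 0.79), Wwtr1 without the same 4 libraries (0.44, 0.43, 0.44 and 0.45) and Tuba4a without sham day 4 replicate 4 or sham day 7 replicate 1 (-0.80 and -0.88). All 3 also lost their calls with only the libraries compared (edgeR adjusted p = 0.136, 0.0921 and 0.134) and with the replicate number as a block (edgeR adjusted p = 0.612, 0.808 and 0.808), where the total was 0 (919 at an unadjusted p under 0.05 in edgeR). The block fit compares the fitted levels of replicate 1 between days, not the group means.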

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

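The count of further airway genes and the fits without the libraries with lung transcripts were chosen after these libraries had been seen. In each group of 5 libraries, the highest or lowest library was compared with the spread of the others, which picks about 1 in 20 groups by chance. Of 438 groups of values tested, 19 stood apart, where 21.9 are expected by chance.

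Among the list scores, means of log2 CPM with 1 added, sham day 7 replicate 2 lay below the others of its group for the respiratory chain and TCA cycle, at 10.04. It lay above them for phagocytic macrophage genes at 5.72, for myofibroblast genes at 5.33 and for collagens at 6.60. MI day 4 replicate 2 lay below its group for inflammatory monocyte genes at 4.52 and for atrial genes at 5.29. MI day 2 replicate 4 lay below for T cell genes at 0.42, and MI day 4 replicate 4 below for immediate-early genes at 5.16. Sham day 4 replicate 1 lay above its group for erythroid genes at 8.33. MI day 7 replicate 2 lay above for lung genes at 7.27, and MI day 7 replicate 4 above for skeletal muscle genes at 7.32, where the other libraries of the group had medians of 1.25 and 2.22.

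Single genes stood apart in the same way. Nppa was low in MI day 4 replicate 2 at 1286 CPM, Myh6 and Ankrd1 in MI day 7 replicate 1 at 4709 and 3029 CPM, and Acta2 in sham day 7 replicate 5 at 109 CPM. Spp1 and Lyve1 were high in sham day 7 replicate 2 at 27.0 and 38.1 CPM, and Tnc and Mki67 in sham day 4 replicate 3 at 25.6 and 26.7 CPM.

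Tests of the difference itself picked out the 746 genes whose MI effect differed between days 2 and 4 and the 158 between days 4 and 7. Of the 30 genes named at each day, Nppa, Col1a1 and Col3a1 had larger effects at day 4 than at day 2, by 0.98, 1.497 and 1.36 on the log2 scale. Their calls for this difference were not examined under the alternatives.

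In all, 6 libraries of days 4 and 7 passed the limit of 50 CPM of Sftpc and Scgb1a1, at 168 to 1642 CPM. Smaller amounts stood in other libraries, with Sftpc at 22.0 CPM in MI day 7 replicate 3 and Scgb1a1 at 20.5 CPM in replicate 5. Fits without the 6 libraries are therefore not free of lung transcripts. Of 10 further airway genes, 9 had means over 10-fold higher in the 6 libraries than in the others of these days. Among them were Bpifa1, 84.0-fold, and Cxcl15, 146-fold, while Cdh1 was 7.03-fold higher. The 6 libraries were not alike. Cyp2f2, Sec14l3, Wfdc2 and Cdh1 lay above all the others in each of the 6, Bpifa1, Scgb3a2 and Foxj1 in 5, Cxcl15 and Epcam in 4 and Slc34a2 in 3. A candidate explanation is lung or airway tissue in these 6 samples. It was weighed as the source of the MI against sham differences. Without these libraries, 89.7% of all genes called at day 4 and 68.8% of those at day 7 were again called in the same direction. That argues against lung tissue at the level of these 6 libraries as the source of most of these calls. No biological explanation was tested.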

How the results depend on the processing

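The alternatives without lung libraries, near-copies or pseudogenes were chosen after the data were seen. The counts of genes for MI against sham at days 2, 4 and 7 stayed within 1.5 times under all alternatives but the test against a fold change of at least 1.5, where 1208, 2146 and 2733 genes passed. In that test, 19 passed for the difference between days 2 and 4, 11 between days 4 and 7, 668 for sham day 4 against day 2 and 0 for sham day 7 against day 4 (edgeR, 83 at an unadjusted p under 0.05), since it asks for a larger change.

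The difference between days 2 and 4 had 1200 genes in DESeq2, 1796 in limma voom and 475 without a filter. That between days 4 and 7 had 421 in DESeq2, 268 in voom, 84 without a filter and 89 with only the libraries compared. Sham day 7 against day 4 had 110 in DESeq2, 86 in voom, 12 without a filter and 5 with only the libraries compared. The cause was not tested. Without the libraries with lung transcripts, which leaves fewer libraries, the last difference and the sham comparisons had 18, 2253 and 0 genes (edgeR, 690 at an unadjusted p under 0.05 for the 0), and the log2 fold changes of Scgb1a1, Jchain and Igkc in sham day 4 against day 2 were -1.92, -0.88 and -0.87. The median of the complement list at day 4 was 0.92 without them.

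With the replicate number as a replicate block, sham day 4 against day 2 had 568 genes and sham day 7 against day 4 had 0 (edgeR, 919 at an unadjusted p under 0.05). The block terms lie within days, so for the sham comparisons that fit compares the fitted levels of replicate 1 between days. It is no check of these differences between group means. Of 15 MI and sham pairs with the same number, 4 had a residual correlation over 0.1, so that the numbers show no pairing.

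Leaving out each library in turn gave 5865 to 6727, 6825 to 7813 and 7318 to 8095 genes at days 2, 4 and 7, 416 to 1236 and 70 to 294 for the differences between days, and 2905 to 3989 and 0 to 31 for the sham comparisons (edgeR, where 1466 and 1400 genes had an unadjusted p under 0.05 in the fits with 0). The median of the complement list at day 4 ranged from -0.41 to 0.35. Over all alternatives, 5047 values of 217 named gene results kept their side of the threshold, 250 lost and 2 gained a call and 3 reversed. For 196 list results these numbers were 1948, 106, 46 and 2. Values below the threshold could change sign without a change of call, and with one library left out 14 gene values and 22 list values changed sign. Leaving out mitochondrially encoded genes changes nothing, since they had no counts. Changes of 1.5-fold were called in 64, 48 and 44% of simulated genes at days 2, 4 and 7. In these simulations 194 to 214 genes were called, far fewer than in the data, and the adjusted p depends on that number. These shares therefore do not give the sensitivity of the real comparisons, in which changes of this size may still be missed.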

Other observations

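The test of pseudogenes and those of fatty acid oxidation against contractile genes were chosen after the result was seen. Genes named in the next paragraph were also chosen after their values were seen.

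Between days 2 and 7, 105 genes went from lower to higher in MI libraries and 72 from higher to lower, without a test of the difference between these days. The gelatinase Mmp2 had log2 fold changes of -0.83 and 1.53, the collagen Col14a1 of -0.63 and 2.02 and the thrombospondin Thbs2 of -0.59 and 2.49. Tfrc went from 1.30 to -0.54 and the glycerol-3-phosphate dehydrogenase Gpd1 from 0.70 to -1.13.

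Other groupings of the same libraries were drawn and fitted in the same way. At day 2, 1 of 100 groupings, the real one, gave as many genes, 6723 against at most 0 in the others (edgeR). At day 4 it was 1 of 100, with 7597 against at most 1589, and at day 7 1 of 100, with 7976 against at most 1016. For the difference between days 2 and 4, 2 of 60 gave as many, with 746 against at most 1273. For that between days 4 and 7 it was 1 of 60, with 158 against at most 2. Sham day 4 against day 2 had 1 of 60, with 3795 against at most 506, and sham day 7 against day 4 had 1 of 60, with 19 against at most 4. For MI against sham at each day and for the sham comparisons, the share of drawn groupings with as many genes was under 0.05. The groupings for the differences between days moved libraries between days within each arm. That also mixed the difference between the days themselves, so they cannot decide on chance for these totals.

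Sham day 4 and day 2 libraries differed in 3795 genes, and the days also differ in library prefix. Reads of overlapping genes on the other strand are argued against as the source of most of these calls. Exon overlap was not more frequent among called genes other than pseudogenes (odds ratio 0.969, 95% interval 0.889 to 1.06). This pooled test cannot decide for single genes. Pseudogenes were over-represented, with 58.1% of 1151 called and an odds ratio of 5.01 (95% interval 4.43 to 5.67). Of those called, 98.7% moved the same way between MI libraries. A difference between sequencing batches may explain this part, but a difference between days would also move the MI libraries the same way. Of the 2981 protein-coding genes called, 90.8% moved the same way between MI libraries. For both classes of genes, day and batch cannot be told apart, because each day 2 library has the other prefix. Recovery from the operation stays open, untested.

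Fatty acid oxidation genes were lower relative to contractile genes in MI than in sham libraries at day 7, by a within-library difference of list means of -0.49 (SE 0.0756, log2, exact permutation p = 0.00794, adjusted p = 0.0238 over 12 exact tests), with 5 of 5 MI libraries below all sham libraries. At day 4 it was -0.36 (SE 0.125, exact permutation p = 0.00794) with 5 of 5, where branched-chain amino acid catabolism differed by -0.13 (exact permutation p = 0.0317, adjusted p = 0.0544), the respiratory chain by -0.07 (p = 0.214) and ion channels by 0.03 (p = 0.548), and at day 2 it was 0.09 (exact permutation p = 0.365). Part of the day 4 difference rests on sham replicate 1. Its fatty acid oxidation score was 9.25, against 8.52 to 8.97 in the other sham libraries of day 4. Its contractile score was 11.90, against 11.78 to 12.14 in them. At day 7 other lists were lower relative to contractile genes too, ion channels by -0.23 (also -0.23 at day 2), branched-chain amino acid catabolism by -0.24 and the respiratory chain by -0.20, so that the pattern at day 7 is not particular to fatty acid oxidation. A lower share of cardiomyocyte RNA would lower both lists alike and is argued against as the whole cause, as is transcript length, since with it as a term the difference at day 7 was -0.486 (SE 0.0995) across 45 genes, against -0.490 without it. This SE is over genes measured in the same libraries and does not measure the spread between samples. A lower expression of fatty acid oxidation genes relative to contractile genes within the muscle may explain the difference and stays a hypothesis, found on the same data.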
